A study of Mus musculus with 16 samples.

How the data were processed

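RNA of LKR10 mouse lung adenocarcinoma cells was sequenced in 16 libraries, 4 for each combination of hairpin (shGFP, shAnkrd35) and growth type (2D monolayer, 3D in 0.5% methylcellulose). Per the labels, cells were infected with lentivirus carrying the hairpin, selected in puromycin at 4 µg/ml for 48 h and grown for a further 96 h, and libraries were made from oligo(dT)-selected RNA with random hexamers. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.5.1b and edgeR were used with the mm10 genome. The counting program, the gene annotation, the use of strand in counting and the filter on low genes are not given in the sources used here. If strand was not used, reads of overlapping genes on opposite strands cannot be told apart.

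The values deposited by the authors are log2 expression values in 16 columns, 1 per library, and 0 columns belonged to other samples. From the values themselves, each is the log2 of CPM of an effective library size, with a prior count that averages 2 reads added before the log. In every library 100% of the values came out as whole reads within a tolerance of 0.01 reads once the prior was taken off. The whole reads gave the library totals of 13.82 to 28.72 M reads, the CPM levels printed beside folds (reads divided by the effective library size, without the prior) and the read counts of Ankrd35. Every gene except Ankrd35 had at least 1 CPM, with the prior included, in 8 or more libraries. The table had thus been filtered before deposit, and genes below such a limit were not analysed here. In 386 symbols, characters changed by software were restored. Of the symbols, 12218 matched and 103 did not match a gene of the GENCODE M21 annotation of mm10, which gave coordinates (start and end, counted from 1), exonic length and GC content for 99.2% of genes.

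Choices of comparisons, tests, named genes, gene lists and most alternatives were made before the data were examined. That design assumed counts or a linear unit such as CPM, and since the values were on the log2 scale already, no further pseudocount was added. The test was limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, a trend of the variance with abundance and robust fitting (statmod 1.5.0). Genes with at least 1 CPM, with the prior included, in at least 4 libraries were tested, which left 12320 and removed Ankrd35. A cell-means model of the 4 groups over all 16 libraries gave 5 contrasts: shAnkrd35 against shGFP in 2D and in 3D, 3D against 2D with shGFP and with shAnkrd35, and the difference of the hairpin effects, 3D minus 2D. P-values were adjusted by the Benjamini-Hochberg method over genes within a contrast, and rose, fell, higher and lower are used for an adjusted p under 0.05. Each gene's adjusted p and SE in the text come from this fit. Fold changes include the prior and so understate changes of low genes.

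Genes named in the text follow a fixed rule. Ankrd35 came first. For both hairpin contrasts and for 3D against 2D with shGFP, the 8 highest and 8 lowest log2 fold changes past the threshold were taken, with no overlap between the groups, a mean of at least 5 CPM over the 8 libraries and no unnamed gene models. For 3D against 2D with shAnkrd35 the first 3 each way were taken, and for the difference of effects the 6 each way with the smallest p, without the condition on overlap. From each described list up to 4 members with the smallest p were taken, and the most abundant one where needed. A few genes and a list that the rule takes are not reported here, though counts of genes and lists include them. Further members are named only where they go against a list or are shared between comparisons and were chosen after their values were seen.

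The 45 gene lists covered pathways, lineages and markers of macrophages, lymphocytes, fibroblasts, endothelial and erythroid cells. The 42 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Counts of members adjusted over the list alone stand beside those adjusted over all genes where they differ.

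Ankrd35 was compared with exact permutation tests on both sides of CPM over 70 permutations, since the filter had removed it from limma's test, and with ratios of pooled reads with exact 95% intervals, which cover counting error only. The folds of the 4 Y-linked genes were tested for heterogeneity with Cochran's Q on limma's SE, whose p rests on a chi-squared approximation that ignores correlation between genes and is not exact. The steps were tested on simulated data with known changes. In 2D, 71.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, with 4 false calls among 12319 genes. These figures hold only without a GC trend, for genes drawn independently and with 1 spread per gene shared by all groups. The measured spread was unequal, with a median SD on the log2 scale of 0.129 in 2D shAnkrd35 and 0.062 in 3D shGFP. The figures may therefore not hold for the measured 2D libraries. A GC slope was then added equally to all 4 libraries of simulated 2D shAnkrd35. With it there were 2917 false gene calls among 12320 genes, against 17 without the slope and 16 after its removal. Since measured changes follow GC content in every contrast (Spearman's rho 0.41 and 0.22 for the hairpin in 2D and 3D, -0.34 and -0.48 for growth with shGFP and shAnkrd35, -0.31 for the difference of effects), all gene counts may hold many calls of that kind. How many cannot be read from the simulation, since measured GC slopes differed between libraries of a group (range 0.393 in 2D shGFP and 0.238 in 2D shAnkrd35). For the difference of effects the shares recovered were 59.7%, 77.6% and 98.5%.

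Alternatives tried were quantile normalization, no filter, a mean of at least 5 CPM, a pseudocount of 0.1 CPM, a replicate block, a fold of at least 2, fits of only the 8 libraries compared and leaving out each library in turn. After the data were seen these were added: a pseudocount of 1 CPM, library totals without factors, median-of-ratios factors, limma's voom on the recovered reads, leaving out both 2D libraries numbered 1, and removal of a length and GC trend. That trend was fitted in each library as natural splines with 4 degrees of freedom each for log2 transcript length and GC content, on the deviations of genes with a mean log2 CPM above 2, and subtracted, and biology that goes with length or GC would be subtracted with it. edgeR's quasi-likelihood test, DESeq2, sva, upper-quartile and RLE normalization were planned for counts and were not run. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.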

Results

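Messenger RNA was measured in LKR10 cells, a line established from a mouse lung adenocarcinoma. The cells carried a lentiviral short hairpin RNA (shRNA) either against Ankrd35, a gene of the ankyrin repeat domain family, or against GFP as the control. They were grown attached as a monolayer (2D) or suspended in 0.5% methylcellulose, a viscous medium that keeps cells from attaching to a surface (3D). The 4 groups of 4 libraries allowed the hairpins to be compared in each growth type, the growth types to be compared with each hairpin, and the difference between the hairpin effects to be tested. The tests covered 12320 genes. The reads assigned to genes ranged from 13.82 M in replicate 3 of 3D shAnkrd35 to 28.72 M in replicate 4 of 3D shGFP. The group means were 22.02 M for 2D shGFP, 21.76 M for 2D shAnkrd35, 25.36 M for 3D shGFP and 20.45 M for 3D shAnkrd35. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

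The first principal component, with 67.4% of the variance of 10466 genes, parted 3D from 2D, and the second, with 19.4%, parted the hairpins. The first component also followed the GC slope of the libraries within 2D shGFP. There replicate 2 had a slope of -0.085 and a score of -13.25, and replicate 1 had 0.308 and -39.39. Its share of the variance therefore cannot be assigned to growth type alone. Replicates were closest in 3D shGFP, with a median SD over genes of 0.06 on the log2 scale, and farthest apart in 2D shAnkrd35, with 0.13. No library was a copy of another, since the differences within groups exceeded counting noise in every pair (chi-squared per degree of freedom 2.85 to 45.22). Technical repeats could exceed it too, so this does not show separate cultures. Replicate 1 of 2D shAnkrd35 stood apart from its group, with a second-component score of -7.47 against -25.83 to -16.53. Chi-squared per degree of freedom was 33.01 to 45.22 in its pairs within the group, against 4.06 to 11.57 in the other pairs. It also stood apart in transcripts that carry ribosomal RNA-like sequence, which were picked after their values were seen. It had 2110 CPM of Gm23935 and 1420 CPM of Lars2, against 239 to 313 CPM and 197 to 259 CPM in the other 3 libraries of its group.

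**Figure D1:**
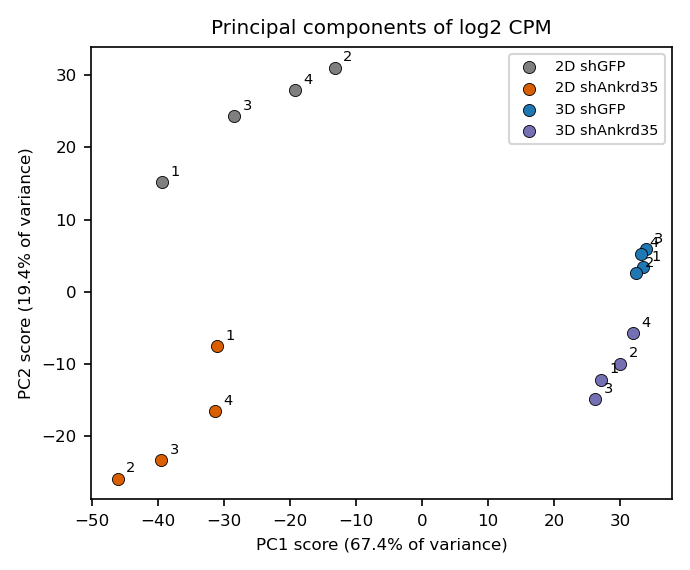
Scores of the 16 libraries on the first and second principal components of log2 CPM, with 1 point per library, colours for the 4 groups and replicate numbers beside the points. The 2D libraries lie at first-component scores of -46.11 to -13.25 and the 3D libraries at 26.24 to 33.83.

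Ankrd35 itself (chromosome 3, 96670131 to 96691032, plus strand, mm10, 14 merged exonic blocks) was the least abundant gene in the table, with a mean of 0.376 CPM. The libraries held 2, 3, 6 and 7 of its reads in 2D shGFP, 2, 6, 7 and 1 in 2D shAnkrd35, 14, 17, 16 and 16 in 3D shGFP and 12, 11, 9 and 9 in 3D shAnkrd35. With the hairpin against Ankrd35 its level was 0.187 ± 0.137 CPM in 2D, against 0.219 ± 0.124 CPM with shGFP (SD, n = 4, two-sided exact permutation p = 0.657). In 3D the levels were 0.501 ± 0.093 and 0.597 ± 0.055 CPM (SD, n = 4, two-sided exact permutation p = 0.143). The ratio of pooled reads was 0.89 in 2D (95% interval 0.42 to 1.85) and 0.81 in 3D (0.54 to 1.23), where the intervals cover counting error only. By counting error alone, a fall to less than 0.42 of the shGFP level was excluded in 2D, and a smaller fall was not detectable at this depth. In 3D the interval excluded a 2-fold fall by counting error alone. A limma fit without the filter, which uses the spread between libraries, gave log2 fold changes of -0.21 ± 0.37 in 2D and -0.23 ± 0.37 in 3D (SE). Growth type moved Ankrd35 more than the hairpin did, with 3D to 2D ratios of 2.80 (1.64 to 5.02) with shGFP and 2.56 (1.41 to 4.89) with shAnkrd35. Both growth comparisons gave an exact permutation p of 0.029, the smallest that 70 permutations allow. Because the targeted transcript did not settle the hairpin labels, the libraries are called labelled shAnkrd35, and each direction given for the hairpin rests on those labels.

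**Figure D2:**
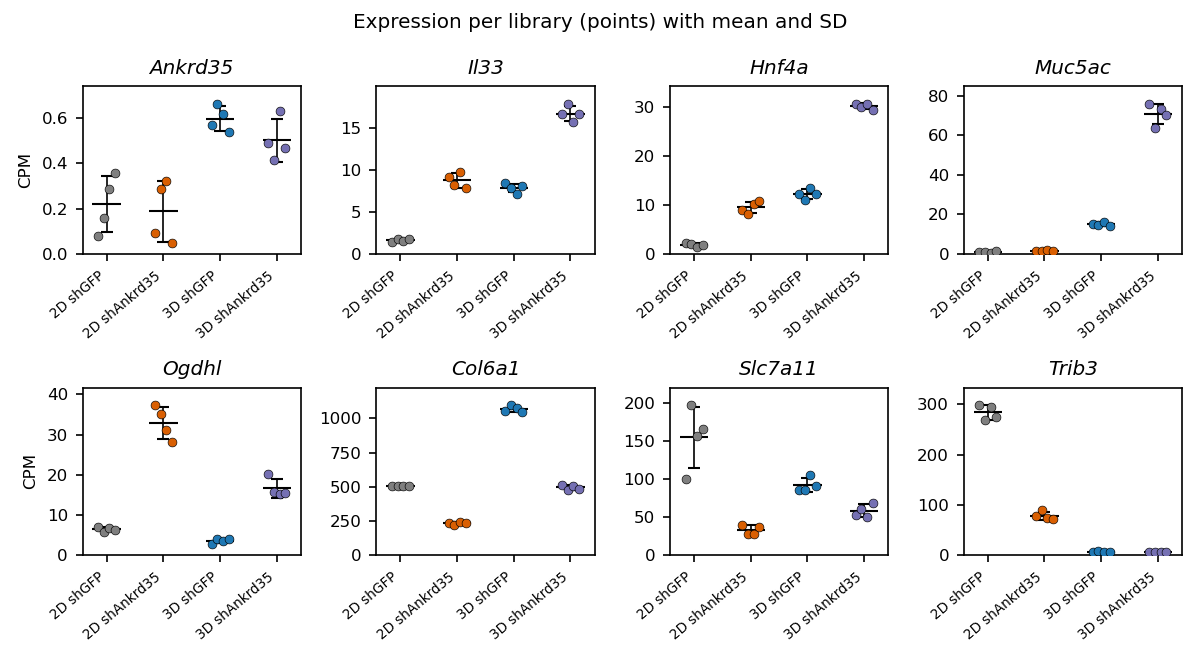
CPM of 8 genes in each library (points), with the mean (horizontal line) and SD (bar) of the 4 libraries of each group. Ankrd35 has group means of 0.187 to 0.597 CPM, while Il33, Hnf4a and Ogdhl are higher, and Col6a1 is lower, in all 4 libraries labelled shAnkrd35 of each growth type.

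In 2D, libraries labelled shAnkrd35 had more RNA of the cytokine Il33, of the endodermal nuclear receptor Hnf4a and of Ogdhl, an oxoglutarate dehydrogenase-like protein, and less RNA of amino acid response genes than shGFP libraries. Il33 (chromosome 19, 29925114 to 29960718) rose from 1.62 ± 0.157 to 8.73 ± 0.892 CPM (SD, n = 4), a log2 fold change of 2.37 ± 0.10 (SE, adjusted p = 1.21e-11). Hnf4a (chromosome 2, 163506808 to 163572910) rose from 1.85 ± 0.339 to 9.52 ± 1.19 CPM and Ogdhl (chromosome 14, 32322019 to 32348151) from 6.48 ± 0.540 to 32.9 ± 4.01 CPM, both by 2.32 ± 0.12 on the log2 scale. The hormone precursor Agt (2.25), the epithelial transcription factor Ehf (1.72), the intestinal cadherin Cdh17 (1.69), the elastase Cela1 (1.53) and Atg9b (1.48) followed. The largest falls by the rule for named genes were in the teneurin Tenm4 (chromosome 7, 96171246 to 96911093, 86.5 ± 7.68 to 17.5 ± 3.03 CPM, log2 fold change -2.31 ± 0.11) and the cystine transporter Slc7a11 (chromosome 3, 49892526 to 50443614, 155 ± 40.2 to 33.3 ± 6.05 CPM, -2.19 ± 0.18). Scara5 (-2.06), Calcrl (-2.05), Fam20a (-2.02), the hypoxia-inducible factor Epas1 (-1.96), Pkhd1l1 (-1.86) and Trib3 (-1.86), a pseudokinase induced by ATF4, also fell.

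Genes of the ATF4 and amino acid response, a program of amino acid synthesis and uptake, fell with the label shAnkrd35 in 2D: 25 of 28 measured members fell and 1 rose, with a median log2 fold change of -0.84 (camera adjusted p = 3.19e-11). Besides Trib3, the amino acid transporter subunit Slc7a5 (-1.61 ± 0.08), the lipoprotein receptor Vldlr (-1.53 ± 0.08) and Mthfd2 (-0.88 ± 0.05), a mitochondrial folate enzyme, had the smallest p. Of 20 ER chaperone and unfolded protein response genes 12 fell and 4 rose (median -0.33, camera adjusted p = 0.00399), among them the chaperone Hspa5 (-0.83) and the transcription factor Xbp1 (-0.73). Gastrointestinal lineage genes rose, with 8 of 13 higher and 1 lower (median 0.71, camera adjusted p = 0.00249). Hnf4a, the protease Ctse (2.23 ± 0.14), Cdh17 and the lectin Lgals4 (1.26 ± 0.11) led that list. These 3 lists also passed with an estimated correlation, each at adjusted p = 0.0476. Wherever a single pair of counts is given for a list, the counts adjusted over the list alone were the same as those adjusted over all genes.

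Extracellular matrix and collagen genes fell in 2D, 18 of 25 being lower and 4 higher (19 and 4 adjusted over the list alone, median -0.63, camera adjusted p = 1.32e-06, and adjusted p = 0.0523 with an estimated correlation). The leading members were Col6a1 (-1.11 ± 0.04), the basement membrane collagen Col4a1 (-0.80), the perlecan gene Hspg2 (-1.19) and Col5a1 (-0.70). Markers of fibroblasts went the same way, with 4 of 8 lower and none higher, including Col6a3 (-2.48), Pdgfrb (-0.86), Meox2 (-2.04) and Pdgfra (-0.84). That call (median -0.74, camera adjusted p = 0.0303, adjusted p = 0.277 with an estimated correlation) was lost without replicate 1 of 2D shGFP (median -0.75, adjusted p = 0.056) or without replicate 1 of 2D shAnkrd35 (-0.75, 0.0543). It was also lost after removal of a length and GC trend (-0.61, 0.0701). In the ankyrin repeat domain family 17 of 26 genes fell and 2 rose (17 and 3 adjusted over the list alone, median -0.37, camera adjusted p = 0.00166, and adjusted p = 0.156 with an estimated correlation). Ankrd27 (-0.76), Ankrd13b (-0.60), Ankrd40 (-0.44) and Ankrd50 (-0.67) led that family.

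Cell cycle genes were higher in 2D libraries labelled shAnkrd35. Of 30 G2 and mitosis genes 18 rose and 3 fell (median 0.34, camera adjusted p = 0.000345, and adjusted p = 0.156 with an estimated correlation). The leading members were the checkpoint kinase Bub1b (0.80), Espl1 (0.65), the anaphase activator Cdc20 (0.85) and Ccnf (0.70). The proliferation marker Mki67, of the same list, fell (-1.04). Of 30 S phase and replication genes 18 rose and 3 fell (20 and 3 adjusted over the list alone, median 0.23, camera adjusted p = 0.00079, and adjusted p = 0.172 with an estimated correlation). Cdc6 (0.67), Rrm1 (0.45), Ccne1 (0.81) and Mcm3 (0.43) rose among them. Oxidative phosphorylation genes rose in 25 of 28 cases with none lower (median 0.37, camera adjusted p = 2.48e-07, and adjusted p = 0.202 with an estimated correlation). Ndufb8 (0.73) and Uqcrc1 (0.52) of the respiratory chain are examples. Lysosome and autophagy genes rose in 18 of 30 cases, with 2 lower (19 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.000345, and adjusted p = 0.177 with an estimated correlation). Its members Ctsa (0.99) and Neu1 (0.89) encode lysosomal enzymes, while Atp6v1a (-0.71), a subunit of the lysosomal proton pump, fell.

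In all, limma called 3575 genes higher and 3554 lower in 2D, of which 263 and 424 changed at least 2-fold. With only the 8 libraries of 2D in the fit, 3052 were higher and 2849 lower. The groups did not overlap for 2749 genes upward and 2159 downward, where chance gives 2.86%. Of 42 lists 8 were called higher and 6 lower, and 3 of the 14 calls held with an estimated correlation. The calls not described above were glycolysis (median 0.19, adjusted p = 0.0045, and adjusted p = 0.374 with an estimated correlation), cholesterol synthesis (0.21, 0.0128, and adjusted p = 0.156 with an estimated correlation), epithelial junctions and keratins (0.40, 0.0153, and adjusted p = 0.0777 with an estimated correlation) and the circadian clock (-0.19, 0.0303, and adjusted p = 0.178 with an estimated correlation). Fold changes in 2D followed gene GC content (Spearman's rho 0.41 across 12217 genes) and transcript length (-0.36), and removal of that trend ended the calls for glycolysis (median 0.07, adjusted p = 0.107) and epithelial junctions (0.25, 0.0565). It left 3618 genes higher and 3385 lower, of which 2620 and 2533 had been called before, and it ended 3 list calls and added 4. It moved the medians of oxidative phosphorylation to 0.22, ATF4 to -0.95, extracellular matrix to -0.50 and gastrointestinal genes to 0.53, and without both 2D libraries numbered 1 the cholesterol (adjusted p = 0.0647) and circadian clock (0.0854) calls were lost. With a mean of at least 5 CPM the epithelial (adjusted p = 0.0598) and circadian clock (0.0643) calls were lost.

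In 3D, libraries labelled shAnkrd35 had more RNA of the gastric protease Ctse and the gel-forming mucin Muc5ac, and less of Grem1, an inhibitor of bone morphogenetic proteins, and the transcription factors Foxf1 and Egr3. Muc5ac (chromosome 7, 141788972 to 141819231) rose from 15.1 ± 0.880 to 70.8 ± 5.15 CPM (SD, n = 4), a log2 fold change of 2.23 ± 0.16 (SE, adjusted p = 1.98e-08). Ctse (chromosome 1, 131638306 to 131675505) rose from 2.64 ± 0.575 to 13.5 ± 1.08 CPM (2.34 ± 0.14, adjusted p = 3.27e-09). Clmn (2.27), Clic6 (2.19), Ogdhl (2.18), Myo15b (2.18) and the mitochondrial creatine kinase Ckmt1 (1.99) also rose. Egr3 fell from 24.7 ± 3.05 to 5.49 ± 0.991 CPM (-2.16 ± 0.20), Grem1 from 14.5 ± 0.615 to 3.93 ± 1.03 CPM (-1.90 ± 0.25) and Foxf1 from 25.5 ± 1.41 to 8.20 ± 1.38 CPM (-1.64 ± 0.10). Ranbp3l (-2.18), the matrix protein Smoc2 (-2.17), the aromatic amino acid transporter Slc16a10 (-1.97), the desmosomal cadherin Dsc2 (-1.70) and the Y-linked helicase Ddx3y (-1.64 ± 0.32, adjusted p = 0.00125) also fell.

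Gastrointestinal lineage genes rose in 3D as well, 8 of 13 being higher and 1 lower (9 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 4.91e-05, and adjusted p = 0.0102 with an estimated correlation). Lgals4 (1.38) and Hnf4a (1.31) were among them, while the intestinal transcription factor Cdx2 fell (-0.74). Cholesterol synthesis genes fell in 10 of 21 cases, with 1 higher (median -0.21, camera adjusted p = 0.00102, and adjusted p = 0.0999 with an estimated correlation). They included Hsd17b7 (-1.57 ± 0.05) and Hmgcs1 (-0.70). Of 19 NF-kB targets and inflammatory cytokines 11 fell and 2 rose (12 and 2 adjusted over the list alone, median -0.31, camera adjusted p = 0.00102, and adjusted p = 0.12 with an estimated correlation). The adhesion molecule Vcam1 (-0.86), the chemokine Ccl2 (-1.07) and Csf1 (-0.39) fell, and Il33 rose (1.08).

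Glycolysis enzymes rose in 11 of 17 cases in 3D, with 1 lower (median 0.21, camera adjusted p = 0.00102, and adjusted p = 0.328 with an estimated correlation). Hk2 (0.69), Gpi1 (0.36), Aldoa (0.34) and Tpi1 (0.28) had the smallest p. Oxidative phosphorylation genes rose in 9 of 28 cases, with 1 lower (10 and 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.00539, and adjusted p = 0.483 with an estimated correlation), for example Sdhb (0.31). Mitochondrially encoded genes rose in 8 of 12 cases with none lower (9 adjusted over the list alone, median 0.37, camera adjusted p = 0.00102, and adjusted p = 0.133 with an estimated correlation), for example mt-Nd6 (0.46) and mt-Co1 (0.34). Their share of reads was 3.11% ± 0.17 in 3D shAnkrd35 and 2.5% ± 0.12 in 3D shGFP (SD, n = 4). Ribosome biogenesis genes rose in 10 of 26 cases, with 1 lower (median 0.12, camera adjusted p = 0.00245, and adjusted p = 0.133 with an estimated correlation), led by the polyamine enzyme Odc1 (0.57) and Nop2 (0.25). NRF2 and oxidative stress genes fell in 10 of 25 cases, with 1 higher (11 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.0184, and adjusted p = 0.25 with an estimated correlation). Catalase (Cat, -0.46) and Osgin1 (-0.63) fell, and the ferritin light chain Ftl1 rose (0.48).

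In all, 1854 genes were higher and 1801 lower in 3D libraries labelled shAnkrd35, of which 157 and 109 changed at least 2-fold, and the groups did not overlap for 2318 genes upward and 2386 downward. With only the 8 libraries of 3D in the fit, 2477 genes were higher and 2611 lower. Of 42 lists 5 were called higher and 6 lower, and the gastrointestinal call held with an estimated correlation. The extracellular matrix (11 of 25 lower and 6 higher, or 13 and 8 adjusted over the list alone, median -0.14, with Col6a1 at -1.11 and Col6a2 at -0.97), ER chaperone (7 of 20 lower, median -0.11) and fibroblast marker (5 of 8 lower and 1 higher, median -0.66, with Pdgfrb at -1.41) lists each passed at adjusted p = 0.0491. Their adjusted p with an estimated correlation was 0.332, 0.133 and 0.328. With only the 8 libraries of 3D in the fit these 3 calls were lost (adjusted p = 0.0879, 0.0594 and 0.0672). With a replicate block the extracellular matrix and fibroblast marker calls were lost too (camera adjusted p = 0.0501 for each). Removal of the length and GC trend ended the ER chaperone call (median -0.05, adjusted p = 0.0759) and added 5 others, and of the gene calls 1679 higher and 1546 lower remained.

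The hairpin effects in 2D and 3D were compared across genes, which are not independent replicates and share no library between the comparisons. Pearson's r of the log2 fold changes was 0.45 with a jackknife SE of 0.08, and Spearman's rho was 0.39. Of 2415 genes called in both growth types 1117 rose in both, 944 fell in both and 354 moved in opposite directions, where independent lists would share 538, 520 and 1057. Col6a1, with a log2 fold change of -1.11 in both, Ogdhl, Hnf4a and Ctse were among the genes that moved alike, and Cdx2 rose in 2D (0.71) and fell in 3D.

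With shGFP, 3D cells had much less RNA of amino acid response genes such as Trib3, Aldh1l2 and Chac1 than 2D cells, and less of p53 targets and actin genes. They had more RNA of mitotic genes, of NF-kB targets and inflammatory cytokines, and of epithelial and gastrointestinal genes. Aldh1l2 (chromosome 10, 83487450 to 83534140), a mitochondrial folate enzyme, fell from 282 ± 9.99 to 7.21 ± 0.526 CPM (SD, n = 4, log2 fold change -5.28 ± 0.07, adjusted p = 1.17e-18). Its exons overlap D10Wsu102e on the other strand, and strand use in counting was not given. Trib3 (chromosome 2, 152337422 to 152344032) fell from 284 ± 14.7 to 7.67 ± 0.316 CPM (-5.19 ± 0.07) and Chac1, an enzyme that degrades glutathione, from 89.0 ± 8.48 to 2.27 ± 0.259 CPM (-5.24 ± 0.13). Tenm4 (-4.84), the actin-binding protein Avil (-4.60), Gpr141 (-4.06) and Angptl6 (-4.00) also fell. Cox6a2, a respiratory chain subunit of muscle, had 10.9 ± 1.42 CPM in 2D and 0 CPM in 3 of the 4 3D libraries. The placental hormone-like gene Prl2c2 (chromosome 13, 12996125 to 13005383) rose from 0.549 ± 0.073 to 59.3 ± 1.25 CPM (6.55 ± 0.10, adjusted p = 9.71e-18). Serpina7 (5.20), Dmbt1 (5.04), Ehf (4.98), Akr1c19 (4.57), Agt (4.52), Akr1c18 (4.27) and Muc5ac (4.13) rose too. Prl2c2 and the Akr1c genes belong to families of similar sequence, so their reads could be split between copies.

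The ATF4 list fell in 25 of 28 members with 2 higher in the growth comparison with shGFP (median -2.03, camera adjusted p = 3.1e-15, and 0.0135 with an estimated correlation), including Mthfd2 (-2.99), Atf5 (-3.19) and Gpt2 (-3.44). Of 18 p53 targets 13 fell and 1 rose (median -0.65, adjusted p = 0.000169, and 0.0135 with an estimated correlation). Plk2 (-2.07), the cell cycle inhibitor Cdkn1a (-1.39), Zmat3 (-1.04) and Sesn2 (-2.28), which the ATF4 list also holds, had the smallest p. YAP and TEAD targets fell in 15 of 19 cases, with 3 higher (median -0.82, adjusted p = 9.82e-05, and adjusted p = 0.0662 with an estimated correlation). Amotl2 (-2.19), Ankrd1 (-2.69) and Ctgf (-2.99) fell among them. Actin and SRF target genes fell in 12 of 18 cases with none higher (median -0.24, adjusted p = 0.00113, and 0.0195 with an estimated correlation). Examples are smooth muscle actin Acta2 (-2.70), Cnn2 (-1.91) and Zyx (-0.77). All 39 cytosolic ribosomal protein genes fell (median -0.52, adjusted p = 1.36e-11, and adjusted p = 0.303 with an estimated correlation). Rps14 (-1.01), Rpl5 (-0.81) and Rps3 (-0.78) led them, and pseudogenes may share their reads.

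G2 and mitosis genes rose in 27 of 30 cases in 3D, with 1 lower (median 0.73, camera adjusted p = 2.13e-07, and 0.0376 with an estimated correlation), including Plk1 (1.03), Ccna2 (0.99), Cdc20 (1.08) and Ccnb1 (0.95). Of 19 NF-kB targets and inflammatory cytokines 13 rose and 1 fell (median 0.83, adjusted p = 0.000534, and 0.0459 with an estimated correlation). The chemokines Ccl2 (3.76) and Ccl7 (3.15) and Il33 (2.22) rose, and Csf1 fell (-1.55). Epithelial junction and keratin genes rose in 11 of 19 cases, with 1 lower (median 0.54, adjusted p = 0.00503, and 0.0375 with an estimated correlation), among them Tjp3 (2.20), Krt19 (1.01) and Elf3 (1.36). Gastrointestinal lineage genes rose in 10 of 13 cases, with 1 lower (median 0.99, adjusted p = 0.000621, and 0.0195 with an estimated correlation), for example Lgals4 (2.82), Hnf4a (2.68) and Cdh17 (2.34). NRF2 and oxidative stress genes rose in 17 of 25 cases, with 4 lower (median 0.61, adjusted p = 0.00261, and adjusted p = 0.123 with an estimated correlation), including the glutathione enzymes Gclc (1.21) and Gsta4 (1.21). All 6 replication-dependent histone genes in the table rose (median 1.0, adjusted p = 0.00917, and adjusted p = 0.0662 with an estimated correlation), for example Hist1h1c (0.90), in RNA selected for poly(A), a tail that most histone messengers lack.

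In all, 4331 genes were higher and 3954 lower in 3D with shGFP, of which 931 and 472 changed at least 2-fold. Non-overlapping groups were seen for 4102 genes upward and 3895 downward. Scaling by library totals alone shifted the median gene by 0.119 on the log2 scale and gave 5569 genes higher and 2927 lower, or 65.5% of calls higher in place of 52.3%. Quantile normalization moved it the other way, to 3855 higher and 4321 lower, or 47.2%. Of 42 lists 6 were called higher and 10 lower, and 7 of these calls held with an estimated correlation. The calls for EMT genes (median -0.37, adjusted p = 0.039, and adjusted p = 0.172 with an estimated correlation), extracellular matrix (-0.59, 0.0195, and adjusted p = 0.278 with an estimated correlation), integrins (-0.21, 0.0431, and adjusted p = 0.624 with an estimated correlation) and ribosome biogenesis (-0.25, 0.00953, and adjusted p = 0.154 with an estimated correlation) were lost under quantile normalization (adjusted p = 0.307, 0.0974, 0.398 and 0.1). Removal of the length and GC trend also ended those for EMT genes (median -0.31, adjusted p = 0.101), extracellular matrix (-0.36, 0.16) and integrins (-0.1, 0.301). Fold changes followed GC content here too (Spearman's rho -0.34 across 12217 genes), and 3472 of the higher and 3425 of the lower gene calls remained after removal.

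**Figure D3:**
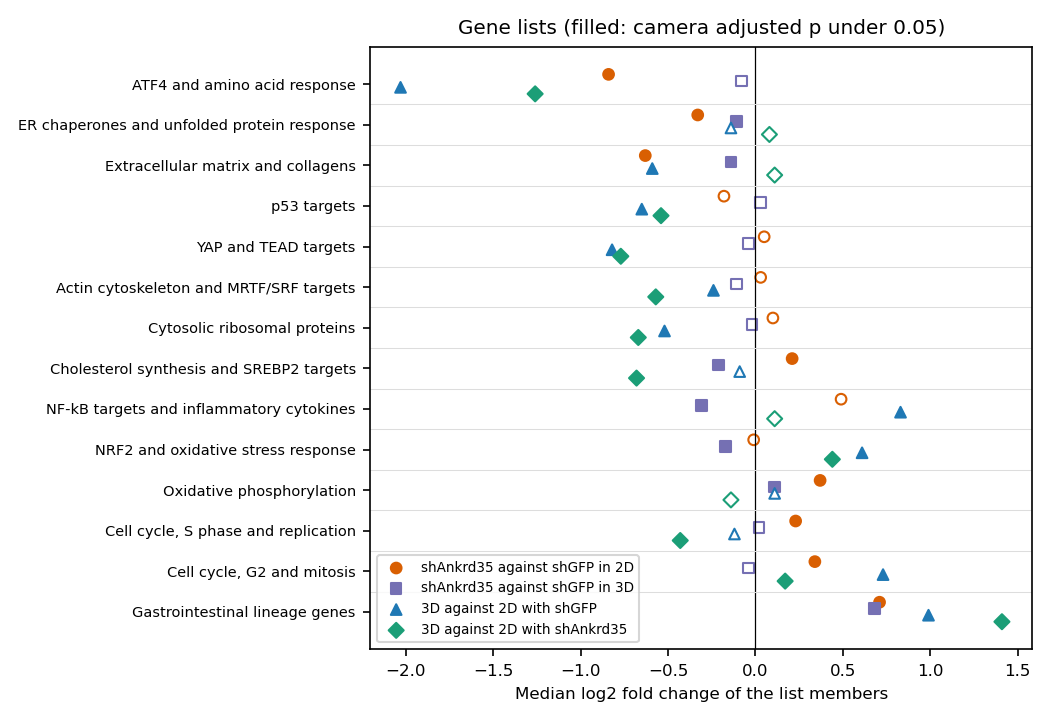
Median log2 fold change of the members of 14 gene lists in the 4 comparisons of groups, with filled symbols where the camera adjusted p was under 0.05. The ATF4 list has medians of -0.84 and -0.08 for shAnkrd35 against shGFP in 2D and 3D, and of -2.03 and -1.26 for 3D against 2D with shGFP and shAnkrd35.

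In libraries labelled shAnkrd35, growth in 3D again went with less RNA of ATF4, p53 and actin genes and more of gastrointestinal genes. Prl2c2 (6.52 ± 0.10), Muc5ac (5.42 ± 0.16, 1.57 ± 0.097 to 70.8 ± 5.15 CPM) and Akr1c19 (5.13 ± 0.30) rose most by the rule, and Aldh1l2 (-5.04 ± 0.07), Chac1 (-4.03 ± 0.13) and the matricellular gene Ctgf (-3.84 ± 0.13) fell most. ATF4 genes fell in 25 of 28 cases, with 2 higher (median -1.26, camera adjusted p = 8.99e-12, and 0.0168 with an estimated correlation). Of 18 p53 targets 13 fell and 2 rose (median -0.54, adjusted p = 0.000516, and 0.0168 with an estimated correlation), for example Gdf15 (-2.46). Actin and SRF target genes fell in 15 of 18 cases with none higher (median -0.57, adjusted p = 2.36e-05, and 0.00963 with an estimated correlation), with Acta2 at -3.58. Gastrointestinal genes rose in 9 of 13 cases, with 1 lower (median 1.41, adjusted p = 0.000929, and 0.0188 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 21 cases, with 2 higher (median -0.68, adjusted p = 5.67e-05, and 0.0188 with an estimated correlation), for example Insig1 (-0.97) and Cyp51 (-0.95).

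S phase and replication genes fell in 24 of 30 cases in 3D libraries labelled shAnkrd35, with 3 higher (median -0.43, camera adjusted p = 0.000315, and adjusted p = 0.129 with an estimated correlation), including E2f1 (-0.77), Cdt1 (-0.82) and Mcm2 (-0.64). G2 and mitosis genes rose in 17 of 30 cases, with 4 lower (median 0.17, adjusted p = 0.0202, and adjusted p = 0.288 with an estimated correlation), for example Ccna2 (0.57) and Mki67 (2.03). YAP and TEAD targets fell in 14 of 19 cases, with 2 higher (14 and 3 adjusted over the list alone, median -0.77, adjusted p = 0.000154, and adjusted p = 0.118 with an estimated correlation), with Ankrd1 at -3.21. Matrix protease and inhibitor genes fell in 12 of 20 cases, with 3 higher (median -0.46, adjusted p = 0.00555, and adjusted p = 0.128 with an estimated correlation), for example Plau (-2.21), Timp3 (-1.67) and Mmp13 (-1.84). NRF2 genes rose in 17 of 25 cases, with 4 lower (median 0.44, adjusted p = 0.0027, and adjusted p = 0.135 with an estimated correlation), and all 39 ribosomal protein genes fell (median -0.67, adjusted p = 7.39e-13, and adjusted p = 0.285 with an estimated correlation).

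In all, 4235 genes were higher and 4441 lower in this comparison, of which 1348 and 351 changed at least 2-fold, and the groups did not overlap for 3678 genes upward and 3611 downward. Library totals alone gave 4999 higher and 3469 lower, or 59.0% of calls higher in place of 48.8%, while quantile normalization gave 3718 higher and 5181 lower, or 41.8%. Of 42 lists 4 were called higher and 12 lower, and 5 of these calls held with an estimated correlation. Glycolysis (median -0.25, adjusted p = 0.0202), EMT genes (-0.28, 0.0332), immediate early genes (-0.47, 0.0202) and mitochondrially encoded genes (0.63, 0.0332) were also called, at adjusted p = 0.428, 0.185, 0.472 and 0.288 with an estimated correlation. Removal of the length and GC trend ended the calls for glycolysis (median 0.01, adjusted p = 0.603) and immediate early genes (-0.27, 0.138) and turned the mitochondrial median to -0.68 (0.064). Quantile normalization ended the calls for EMT genes (-0.22, adjusted p = 0.142) and glycolysis (-0.06, 0.543), and with only the 8 libraries compared the EMT call was lost as well (0.0569). Fold changes followed GC content (Spearman's rho -0.48 across 12217 genes), and 3065 of the higher and 3069 of the lower gene calls remained after trend removal. Across genes the growth effects with the hairpins gave a Pearson's r of 0.81 (jackknife SE 0.06) and Spearman's rho of 0.77. Of 6421 genes called with both hairpins 3043 rose in both, 2979 fell in both and 399 moved in opposite directions, where independent lists would share 1489, 1425 and 2920.

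In the test of the difference between the hairpin effects, 3D minus 2D, NF-kB targets and cholesterol synthesis genes had a negative difference and ATF4 genes a positive one. The hairpin medians of NF-kB targets were 0.49 in 2D, which did not pass (camera adjusted p = 0.072), and -0.31 in 3D. For cholesterol synthesis they were 0.21 in 2D and -0.21 in 3D. ATF4 genes fell with the label shAnkrd35 in 2D and did not pass as a list in 3D (median -0.08, camera adjusted p = 0.328, with 9 of 28 lower and 5 higher). The difference was positive for 22 of the 28 genes and negative for 1 (23 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 1.18e-12, and 0.0138 with an estimated correlation), for example Slc7a5 (1.57), Vldlr (1.44) and Gpt2 (1.21). Trib3 fell from 284 to 78.3 CPM with the label in 2D and had 7.67 ± 0.316 and 6.44 ± 0.416 CPM in 3D (difference 1.61 ± 0.10, adjusted p = 1.19e-08). NF-kB targets had a negative difference in 15 of 19 cases and a positive one in 1 (median -0.69, adjusted p = 1.62e-06, and 0.0138 with an estimated correlation), for example Ccl2 (-1.63), Il33 (-1.29) and Nfkbia (-0.79). Cholesterol synthesis genes had a negative difference in 16 of 21 cases and a positive one in 1 (median -0.46, adjusted p = 1.86e-08, and 0.00911 with an estimated correlation), for example Insig1 (-0.87), Hsd17b7 (-0.89), Acat2 (-0.90) and Nsdhl (-0.92). G2 and mitosis genes were negative in 18 of 30 cases and positive in 2 (18 and 3 adjusted over the list alone, median -0.42, adjusted p = 5.17e-06, and adjusted p = 0.0908 with an estimated correlation), for example Cdc20 (-0.89). Extracellular matrix genes were positive in 12 of 25 cases and negative in 2 (median 0.40, adjusted p = 0.000184, and adjusted p = 0.116 with an estimated correlation), for example Lamb3 (1.14) and Hspg2 (0.90).

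Among single genes the smallest p for a positive difference were those of Tenm4 (3.26 ± 0.16), the transcription factors Klf4 (1.39) and Myrf (1.21), Trib3, the ER oxidase Ero1l (1.57) and the protease Mmp28 (1.11). For a negative difference they were those of the lysophospholipase Enpp2 (-1.45 ± 0.08), Padi4 (-1.76), the claudin Cldn2 (-0.91), the creatine kinase Ckb (-1.32), the growth factor-binding protein Igfbp3 (-1.50) and the receptor Cd14 (-0.80). In all, 2110 genes had a positive and 2297 a negative difference, and 6 lists were called positive and 11 negative, of which 3 calls held with an estimated correlation. Removal of the length and GC trend ended the oxidative phosphorylation call (median -0.27 to -0.04, adjusted p = 0.000165 to 0.644, and adjusted p = 0.328 with an estimated correlation before removal). It also ended those for matrix proteases (median -0.26 to -0.14, adjusted p = 0.0417 to 0.133), mitochondrially encoded genes (0.39 to 0.07, adjusted p = 0.0351 to 0.86) and immediate early genes (-0.38 to -0.27, adjusted p = 0.0468 to 0.179), whose adjusted p with an estimated correlation was 0.231, 0.299 and 0.572 before removal. It turned that of the ribosomal proteins (median -0.11 to 0.13, adjusted p = 0.0483 to 0.00118, and adjusted p = 0.787 before and 0.162 after removal with an estimated correlation). Fold differences followed transcript length (Spearman's rho 0.43 across 12217 genes) and GC content (-0.31), and 1561 of the positive and 1539 of the negative gene calls remained after removal. Leaving out both 2D libraries numbered 1 raised the counts to 3358 positive and 2995 negative.

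Markers of lymphocytes, erythroid cells and macrophages were rare in the table, while 8 of 16 fibroblast markers were measured. None of 16 lymphocyte markers and only Epor of 11 erythroid markers were measured, and the macrophage list had 4 of 18 members, Cd14, Mrc1, Cd68 and Lyz2, so these lists were not tested as groups. Cd14, with a mean of 89.8 CPM over all libraries, was higher in 3D than in 2D with shGFP (1.59 ± 0.04, adjusted p = 3.59e-15) and higher with the label shAnkrd35 in 2D (0.98 ± 0.04, adjusted p = 2.41e-11), while Lyz2, at 2.6 CPM, differed by -0.34 ± 0.76 and 0.96 ± 0.76. Endothelial markers, with 5 of 16 measured, had 4 higher and none lower with the label in 2D but did not pass as a list (median 0.45, camera adjusted p = 0.101). The most abundant of them, Flt1, had a mean of 105.2 CPM and rose with 3D growth (0.97 ± 0.07 with shGFP).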

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

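Removal of the length and GC trend and the omission of 2 libraries were chosen after the results were seen, while the splits of libraries, the difference of hairpin effects and the search for stray libraries were fixed earlier. With the label shAnkrd35 the effect differed between 3D and 2D in 2110 genes upward and 2297 downward. Among 100 regroupings of the libraries 2, the real one included, called as many genes as the real 4407, and the highest other one called 5226. That regrouping kept the 2D labels and exchanged 3 of the 4 3D libraries of each hairpin, so it adds the 2D effect to a reversed 3D effect. In 2D the real split of the 35 called 7129 genes and 1 split, itself, called as many, the highest other one calling 4586. In 3D 1 of 35 splits called as many as the real 3655, and the highest other one called 0. For growth with shGFP 1 of 35 called as many as the real 8285, with 0 in the highest other one, and with shAnkrd35 1 of 35 called as many as the real 8676, with 1802. For the 4 contrasts between groups, a chance arrangement of these libraries can be excluded at the 0.05 level. Chance between cultures cannot, since the libraries may be technical repeats. For the difference of effects the regroupings cannot decide. Exchanging hairpin labels within a growth type tests for no hairpin effect at all, not for equal effects in 2D and 3D. For no comparison can the splits say more than that.

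Single genes with a positive difference were Tenm4 (3.26), Klf4 (1.39), Myrf (1.21), Trib3 (1.61), Ero1l (1.57) and Mmp28 (1.11), and those with a negative one were Enpp2 (-1.45), Padi4 (-1.76), Cldn2 (-0.91), Ckb (-1.32), Igfbp3 (-1.50) and Cd14 (-0.80). List medians of the difference were positive for extracellular matrix (0.40), ATF4 (0.62), ER chaperones (0.34), ribosome biogenesis (0.18), mitochondrially encoded genes (0.39) and the ankyrin repeat family (0.24). Of these only ATF4 held with an estimated correlation (adjusted p = 0.0138), the others having adjusted p = 0.116, 0.116, 0.241, 0.299 and 0.143 in the same order. They were negative for S phase (-0.26), G2 and mitosis (-0.42), oxidative phosphorylation (-0.27), cholesterol synthesis (-0.46), fatty acid genes (-0.19), NF-kB targets (-0.69), actin (-0.23), matrix proteases (-0.26), lysosome (-0.25), ribosomal proteins (-0.11) and immediate early genes (-0.38). Cholesterol synthesis (adjusted p = 0.00911) and NF-kB targets (0.0138) held with an estimated correlation. The others did not, with adjusted p = 0.18 for S phase, 0.0908 for G2 and mitosis, 0.328 for oxidative phosphorylation, 0.422 for fatty acid genes, 0.082 for actin, 0.231 for matrix proteases, 0.18 for lysosome, 0.787 for ribosomal proteins and 0.572 for immediate early genes. After removal of the length and GC trend the medians of mitochondrially encoded genes (0.07, adjusted p = 0.86), oxidative phosphorylation (-0.04, 0.644), matrix proteases (-0.14, 0.133) and immediate early genes (-0.27, 0.179) no longer passed, and that of ribosomal proteins turned to 0.13 (adjusted p = 0.00118, and adjusted p = 0.162 with an estimated correlation). Without both 2D libraries numbered 1 the calls for ER chaperones (adjusted p = 0.14), ribosome biogenesis (0.0884) and fatty acid genes (0.116) were lost. ER chaperones were lost without replicate 1 of 2D shGFP (0.0564) or of 2D shAnkrd35 (0.1) alone. Matrix proteases, ribosomal proteins and immediate early genes were also lost under quantile normalization (adjusted p = 0.0561, 0.228 and 0.0551) and with a mean of at least 5 CPM (0.0931, 0.071 and 0.0808). With a replicate block the matrix protease call was lost as well (camera adjusted p = 0.0503).

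Stray libraries were seen for 7 of the named genes in 8 of 148 group tests, which is near the 5% that chance gives. Tenm4 had 98.0 CPM in replicate 3 of 2D shGFP (82.4 to 83.0 in the other 3) and Scara5 36.7 CPM in replicate 2 of that group (32.9 to 33.3). Ogdhl had 20.2 CPM in replicate 1 of 3D shAnkrd35 (15.2 to 15.7), and Akr1c19 had 18.6 CPM there (21 to 21.3) and 14.8 CPM in replicate 4 of 3D shGFP (up to 21.4 in the others). In 3D shGFP, Cox6a2 had 0.0407 CPM in replicate 1 (0 in the others), Angptl6 1.29 CPM in replicate 2 (1.02 to 1.04) and Igfbp3 47.3 CPM in replicate 3 (51.1 to 51.7). No library was removed for these values, and their cause was not tested.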

How the results depend on the processing

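A fold of at least 2 left 263 genes higher and 424 lower with shAnkrd35 in 2D, 157 and 109 in 3D, 931 and 472 for growth with shGFP, 1348 and 351 for growth with shAnkrd35, and 317 and 150 for the difference of effects. Fits of only the 8 libraries compared gave 3052 genes higher and 2849 lower with shAnkrd35 in 2D, and 2477 and 2611 in 3D. The hairpin counts of the growth types thus lay closer together than in the main fit, where all groups share 1 spread per gene. Without both 2D libraries numbered 1, which was tried after the splits were seen, 3358 genes had a positive and 2995 a negative difference. After removal of the length and GC trend, with or without a replicate block, the median of the mitochondrially encoded genes for growth with shAnkrd35 reversed to -0.68 and that of the ribosomal proteins in the difference of effects reversed to 0.13. The cause was not tested. Leaving out single libraries gave 3197 to 3861 genes higher and 3082 to 3922 lower in 2D, 1506 to 1736 and 1473 to 1597 in 3D, 4026 to 4391 and 3703 to 3895 for growth with shGFP, 4012 to 4412 and 4161 to 4630 for growth with shAnkrd35, and 1579 to 2852 and 1823 to 2897 for the difference. Pearson's r of the hairpin effects lay between 0.409 and 0.492 and that of the growth effects between 0.769 and 0.836. With the replicate block 3499 genes were higher and 3468 lower in 2D, 1748 and 1700 in 3D, 4259 and 3897 for growth with shGFP, 4204 and 4385 with shAnkrd35, and 1891 and 2121 for the difference. Replicate numbers gave no sign of pairing samples, since in 5 of 24 comparisons between groups the library of the same number was the closest, where chance gives 6. edgeR's quasi-likelihood test, DESeq2, sva, upper-quartile and RLE normalization were not run.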

Other observations

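Tests on trend removal, on 2 libraries numbered 1, on the 2D and 3D bounds of Ankrd35, on the Y-linked genes after trend removal and on the heterogeneity of their 2D folds were chosen after the results were seen. Of 8 lung basal and squamous genes 4 were lower in 2D and none higher, with Pkp1 (-0.86) and Trp63 (-0.86) in front, and the list did not pass (median -0.54, camera adjusted p = 0.0763). It passed after removal of the length and GC trend (median -0.64, camera adjusted p = 0.0305, and adjusted p = 0.121 with an estimated correlation), and its median in 3D was -0.38 (camera adjusted p = 0.186). Of 9 alveolar type 2 genes 3 were higher and 1 lower (median 0.07, camera adjusted p = 0.706), Foxa1 rising (0.61) and Cebpa falling (-0.43). In 3D the immediate early genes had 6 of 22 lower and 1 higher (median -0.22, camera adjusted p = 0.0512, and adjusted p = 0.629 with an estimated correlation). That list passed with a replicate block (adjusted p = 0.0268) and after trend removal (0.0244, and adjusted p = 0.457 with an estimated correlation). Vwf, an endothelial marker, rose in 2D (1.66) and in 3D (1.41).

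The 4 Y-linked genes of the table were lower with the label in both growth types before trend removal. Ddx3y changed by -1.74 in 2D and -1.64 in 3D, Eif2s3y by -0.96 and -1.39, Kdm5d by -0.42 and -1.12 and Uty by -0.87 and -1.12. After removal of the length and GC trend Kdm5d (-0.03, adjusted p = 0.878) and Uty (-0.02, adjusted p = 0.947) no longer passed in 2D. Their X-linked counterparts changed less, Ddx3x by -0.87 and -0.20 and Kdm6a by -0.39 and -0.17. Between 3D and 2D the Y-linked genes had medians of 1.66 with shGFP and 1.34 with shAnkrd35, where Kdm5d did not pass (0.17, adjusted p = 0.256). After removal of the length and GC trend the growth changes with shAnkrd35 were 0.37 for Ddx3y, 0.63 for Eif2s3y, -0.37 for Kdm5d and -0.52 for Uty. With shGFP they were 0.97, 1.26, 0.7 and 0.5 in the same order.

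Ankrd35 reads were not clearly fewer with its own hairpin. In 2D the lower bound of the ratio was 0.42, so too few reads may explain why no 2-fold fall was seen. In 3D the lower bound was 0.54, which by counting error alone excludes a 2-fold fall in RNA but not a smaller one. That bound leaves out the spread between libraries. Exchanged labels in 1 growth type are unlikely, since the lowest Pearson's r of the hairpin effects without a library was 0.45 after trend removal. An exchange in both growth types, or a loss of protein without a loss of RNA, was not tested. With no clear fall of Ankrd35 RNA, the data do not show that the other changes with the label follow from a loss of Ankrd35.

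A smaller share of cells with a Y chromosome could not be excluded as a cause of the low Y-linked genes in 3D. There the folds of the 4 genes were not found to differ (heterogeneity p = 0.42 by a chi-squared approximation, not an exact test). The SE in that test, 0.13 to 0.32, rest on the spread of all 16 libraries, so modest differences could be missed. In 2D the folds did differ (heterogeneity p = 0.001 by the same approximation, not an exact test). That p rests on the same SE and may be too small where the 2D spread was wider. Ddx3y, for example, had an SD of 3.06 CPM at a mean of 6.33 in 2D shGFP, and of 0.27 at 21.2 in 3D shGFP. A smaller share of such cells is thus unlikely to be the whole cause in 2D but is not excluded. Shared depth or scaling is unlikely, as the X-linked counterparts had a median of -0.36 in 2D, where they came nearest. After removal of the length and GC trend the Y-linked median was -0.32 in 2D, so the trend may account for much of the 2D fall, and -1.17 in 3D, where it could not. The cause stays open.

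Fold changes in 2D followed GC content, and differences between single libraries may be the source, since the GC slope ranged over 0.393 within a group against 0.263 between the group means. Removal of the trend ended 3 list calls in 2D. For the lists named next the trend is unlikely to be the whole cause. Their medians after its removal were 0.22 for oxidative phosphorylation, -0.95 for ATF4, -0.50 for extracellular matrix, 0.53 for gastrointestinal genes and 0.39 for G2 and mitosis. With an estimated correlation ATF4 (adjusted p = 0.01), extracellular matrix (0.0407) and gastrointestinal genes (0.0491) passed after removal. Oxidative phosphorylation (0.121) and G2 and mitosis (0.0799) did not. Exchanging replicates 1 of the 2D groups called 4586 genes, and exchanged labels are an unlikely cause, since over the genes changed in 3D replicate 1 of 2D shGFP scored -0.45, within the range of its own group, although replicate 1 of 2D shAnkrd35 scored 0.32, with the sign of its group but below its 0.46 to 0.52. After removal of the length and GC trend this exchanged split called 2335 genes. The exchange leaves all libraries but replicate 1 of each 2D group in place, so part of the hairpin difference stays in it. The count therefore cannot decide whether the trend alone made this split stand out. Removal of the trend may also take away biology that goes with length or GC.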
